A study of Homo sapiens with 9 samples.

How the data were processed

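The authors deposited 1 table of whole-number counts per gene for 9 libraries, with no normalization. The labels' protocols describe poly(A) RNA selected with oligo-dT beads and strand-marked libraries made with dUTP. The treatment protocol also names HOXC6 shRNAs, which are not among these samples, and an expression array, whereas these are sequencing libraries. The submitters' processing notes name STAR 2.5.2b, R 3.3.1, DESeq2 1.14.1 and the GRCh38 build, without a role for each. The counting program, the annotation release and the strand setting are not given in the sources used here. Each of the 9 columns of counts was matched to a library by its name, and 0 columns were left unused.

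The table held 58096 Ensembl gene IDs, of which 57492 (99.0%) were matched without their version number to GENCODE release 29 on GRCh38, and 604 were not matched. Symbols, coordinates and overlaps with other genes come from that match. Pseudogenes took between 6.00% and 6.38% of the counts of a library. EEF1A1P5 held a mean of 103906 counts beside 188662 for EEF1A1, so genes with near-identical copies are uncertain. Because the strand setting is not known, genes with an overlapping partner are uncertain too.

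Total counts per library ran from 22666737 to 28345357. Replicate pairs within a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.60 to 16.85 over genes with 50 or more counts in the pair, so each library was counted as 1 replicate. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

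The main test was the edgeR 4.0.16 quasi-likelihood F-test, two-sided, with TMM scaling, the filterByExpr filter by group and default dispersion settings, in R 4.3.3. All 9 libraries entered 1 model with 3 groups, which share 1 estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and 18564 genes were tested. The standard error (SE) of a log2 fold change is its absolute value divided by the square root of F. Levels are CPM, the TMM-scaled counts relative to library size. Gene lists were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over 82 tests of 41 lists in 2 comparisons, and adjusted separately over the 41 lists for the difference between the 2 shRNAs. Each camera test was repeated with an estimated correlation, and fry was run as well. Of 42 lists written, 1 had fewer than 3 tested members. Per-library list levels are means of log2(CPM + 1), compared with an exact permutation test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.

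The groups, the tests of genes and lists, the gene lists, all alternatives but 1 and the rule for named genes were fixed before the data were examined. The rule named KLF7, DLG3 and HOXC6 always, and otherwise only genes with a mean CPM of at least 1 and a symbol that is not clone-based. For both shRNAs it took the 12 higher and 12 lower genes with the largest smaller change, past the threshold in both comparisons, with all 6 KLF7 shRNA libraries beyond all 3 controls. For each shRNA it took the 5 higher and 5 lower genes with the largest change past the threshold there and not in the other. For the difference between the shRNAs it took up to 5 in each direction, and for each list up to 4 members, or 8 for the interferon and Golgi lists. Not every gene that this rule took is reported here.

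The edgeR and camera steps were tested on simulated counts, in 1 draw each. With 200 genes changed in both KLF7 shRNA groups and 18312 genes tested, the test of KLF7 shRNA 1 recovered 26% of 1.25-fold, 60% of 1.5-fold, 80% of 2-fold and 96% of 3-fold changes and called 10 unchanged genes. The test of KLF7 shRNA 2 recovered 30%, 72%, 86% and 96% of the same sizes and called 15 unchanged genes. Alternatives were edgeR RLE and upper-quartile factors, no low-count filter, a filter of CPM above 1 in at least 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, fits on only the libraries compared, a 2-group fit, an adjusted p under 0.01 and each library left out in turn.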

Results

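RNA was sequenced from PANC1, a human pancreatic ductal adenocarcinoma cell line, expressing a non-silencing control shRNA or 1 of 2 short hairpin RNAs against KLF7, a Krüppel-like transcription factor. The groups are named control shRNA, KLF7 shRNA 1 and KLF7 shRNA 2, with 3 libraries each. Total counts were 28275381, 24163381 and 23687936 in the control libraries, 25265302, 22666737 and 26952238 with KLF7 shRNA 1, and 23526326, 28345357 and 27422589 with KLF7 shRNA 2. Mitochondrial transcripts took 6.17% ± 0.639 (SD, n = 3) of the counts in the control, 5.79% ± 0.452 (SD, n = 3) with KLF7 shRNA 1 and 5.54% ± 0.417 (SD, n = 3) with KLF7 shRNA 2.

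The first question was how far each hairpin lowered its target. KLF7 (ENSG00000118263.14, GRCh38 chromosome 2, 207074137 to 207167267) stood at 15.3 ± 0.462 CPM in the control (SD, n = 3). It stood at 12.5 ± 0.420 CPM with KLF7 shRNA 1 and 11.0 ± 1.57 CPM with KLF7 shRNA 2 (SD, n = 3 each). All 6 KLF7 shRNA libraries lay below all 3 controls. KLF7 fell with KLF7 shRNA 2 (log2 fold change −0.48, SE 0.10, edgeR adjusted p = 0.0203). With KLF7 shRNA 1 the log2 fold change was −0.30 (SE 0.10), which did not pass the threshold (edgeR adjusted p = 0.126). The call for KLF7 shRNA 2 was lost without control shRNA replicate 1B (edgeR adjusted p = 0.0920) or 2B (0.0701), or without KLF7 shRNA 2 replicate 1 (0.0610) or 2 (0.110). HOXC6, a homeobox gene named in the treatment protocol, had log2 fold changes of 0.02 and −0.01 with SE 0.07 each, and it overlaps other HOXC genes.

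**Figure D1:**
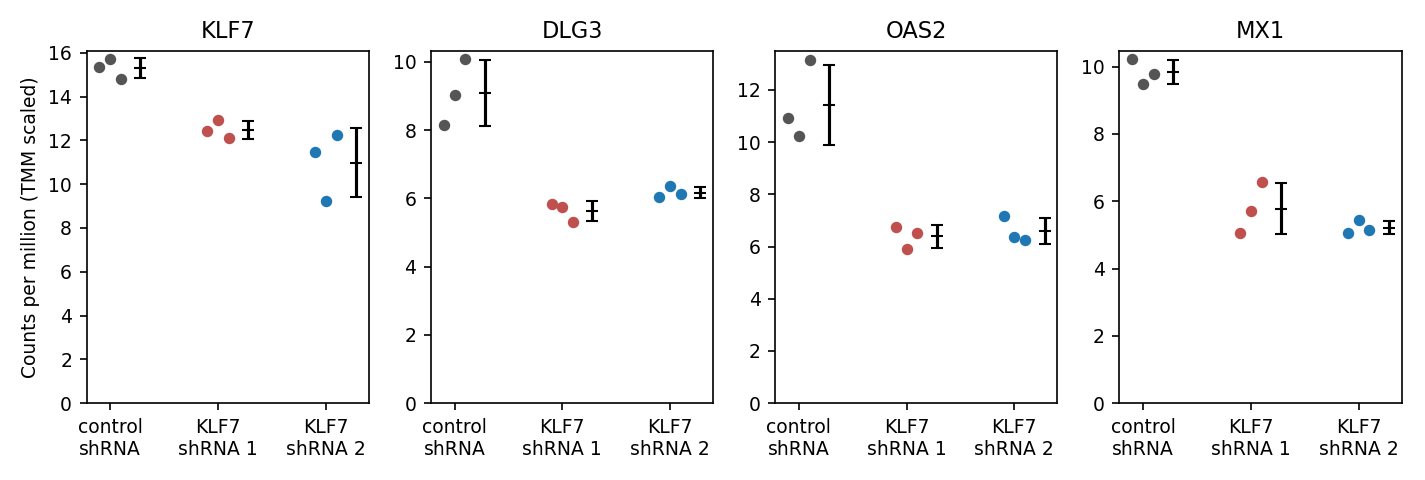
CPM (vertical axis, TMM scaled, from 0) of KLF7, DLG3, OAS2 and MX1 in each library of the 3 groups (horizontal axis). Points are libraries and bars are the mean ± SD of 3 libraries. For each of these genes the 6 KLF7 shRNA libraries lie below the 3 controls, as for KLF7 at 15.3, 12.5 and 11.0 CPM on average.

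The design asks which genes both hairpins changed. Below, 2 values after a gene are its log2 fold changes with KLF7 shRNA 1 and KLF7 shRNA 2, n = 3 libraries per group. Interferon-stimulated genes such as OAS2 and MX1 fell with both, while FOS, NRG1 and MMP2 were among the genes that rose. Of 428 genes changed with KLF7 shRNA 1 and 301 with KLF7 shRNA 2, 186 were shared, and each of these had the same sign in both. The shared genes were 100 higher and 86 lower, with a median absolute log2 fold change of 0.49. Independent lists of these sizes would share 1.81 higher and 1.62 lower genes, and 30 simulations of unchanged groups against the same controls shared 1 gene at most. In simulations without changed genes few can be called, so their count does not show how much of the overlap the controls give. The log2 fold changes of all tested genes correlated at 0.613 across genes, which are not independent replicates, against 0.504 in the simulations. Their covariance was 0.0371 against 0.0170 simulated, while 66.7% of the tested genes had the same sign in both comparisons against 66.8% simulated. No division of 3 control libraries leaves at least 2 for each hairpin, so part of the excess in shared genes and in the correlation may come from the shared controls. Without control shRNA replicate 1B 88 genes were shared, and without KLF7 shRNA 2 replicate 1, 2 or 3 the counts were 117, 107 and 100.

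**Figure D2:**
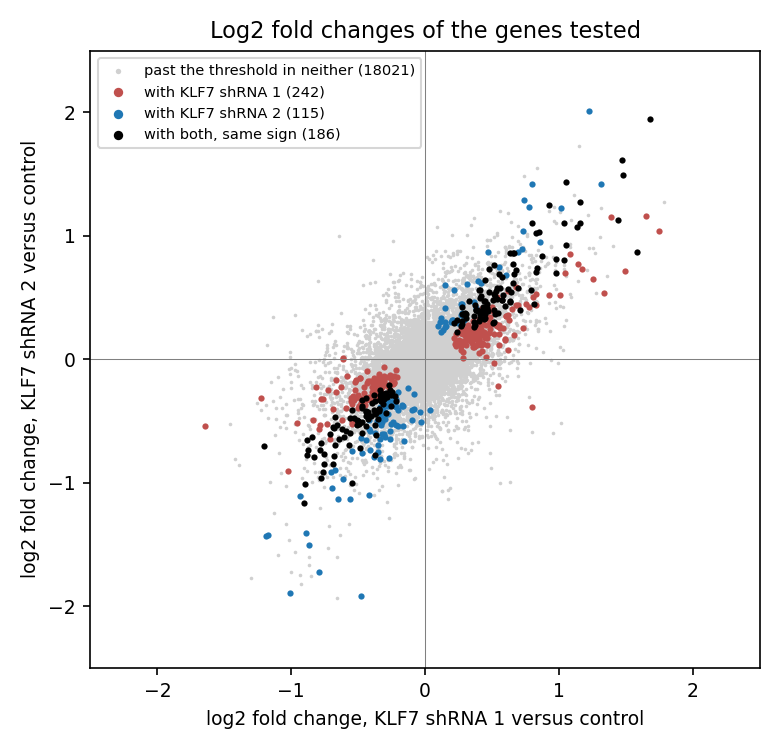
Log2 fold change of each tested gene with KLF7 shRNA 1 (horizontal axis) and with KLF7 shRNA 2 (vertical axis) against the control. Black points are the 186 genes past the threshold with both in the same direction, coloured points the genes past it with 1 shRNA, and 1 gene past the threshold in neither lies outside the axes. The black points lie at the lower left and the upper right.

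Interferon-stimulated genes, which cells switch on in response to interferon, were lower with both hairpins. Of 52 tested members, 13 fell and 0 rose with KLF7 shRNA 1, and 13 fell and 0 rose with KLF7 shRNA 2. Adjusted over the list alone, 20 fell and 1 rose with KLF7 shRNA 1, and 23 fell and 0 rose with KLF7 shRNA 2. The list's mean log2 fold change was −0.27 (median −0.25, SD 0.27 over members) with KLF7 shRNA 1 and −0.32 (median −0.27, SD 0.31) with KLF7 shRNA 2. Camera gave adjusted p = 3.79e-17 and 9.73e-25, and adjusted p = 0.00677 and 0.00520 with an estimated correlation. OAS2 and OASL, of the oligoadenylate synthetase family, fell by −0.83 and −0.75 with KLF7 shRNA 1 and by −0.79 and −0.76 with KLF7 shRNA 2. The antiviral GTPase MX1 fell by −0.76 (SE 0.10) and −0.91 (SE 0.10), and IFI6 by −0.68 and −0.78 (SE 0.11 each). HERC5, an ISG15 ligase, fell by −0.62 and −0.56, IFIT1 by −0.56 and −0.48, IFITM1 by −0.51 and −0.53, and IFIT3 by −0.44 and −0.43. The SE of these log2 fold changes were 0.06 to 0.11, and these 8 genes stayed past the threshold without each library in turn. MX1 overlaps a gene on the other strand and IFITM1 overlaps IFITM2. The levels per library were lower in 6 of 6 KLF7 shRNA libraries than in each control, by 0.24 on the log2(CPM + 1) scale. The exact permutation test, two-sided, gave p = 0.0238, the smallest that 6 against 3 allows (adjusted p = 0.0697 over 41 lists). Such a separation, with the same p, was not particular to this list. It was also seen for lists with small differences, among them ER chaperones and ERAD (0.0237 higher) and p53 target genes (−0.062).

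Outside that list, the lower genes with the largest changes had several known roles. SLIT1, an axon guidance ligand, fell by −0.90 (SE 0.12) with KLF7 shRNA 1 and −1.17 (SE 0.13) with KLF7 shRNA 2. PDCD4, a translation inhibitor, fell by −0.88 and −0.78, and the stress-induced NUPR1 by −0.78 and −0.96. DEPTOR, an mTOR inhibitor, fell by −0.87 and −0.74, the pyruvate dehydrogenase kinase PDK3 by −0.79 and −0.74, LYSMD2 by −0.75 and −0.85, and the tetraspanin TSPAN33 by −0.69 and −0.85. RNF144A-AS1 fell by −0.89 and −1.01 (SE of these genes 0.08 to 0.20). DLG3 (ENSG00000082458.11, GRCh38 chromosome X, 70444861 to 70505490), a scaffold protein of the MAGUK family, stood at 8.14, 9.04 and 10.1 CPM in the 3 controls, and fell to 5.64 ± 0.291 with KLF7 shRNA 1 and 6.17 ± 0.168 with KLF7 shRNA 2 (SD, n = 3 each). Its log2 fold changes were −0.69 (SE 0.10, edgeR adjusted p = 0.00248) and −0.55 (SE 0.10, edgeR adjusted p = 0.0105). The second call was lost without any 1 of the KLF7 shRNA 2 libraries (highest edgeR adjusted p = 0.0718). SLIT1, PDCD4, LYSMD2, DEPTOR and DLG3 overlap annotated neighbours and are uncertain to that extent. TSPAN33 with KLF7 shRNA 1 (highest edgeR adjusted p = 0.0548) and RNF144A-AS1 with both (0.120 and 0.116) did not keep their calls without each library.

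The higher genes with the largest changes rose 2-fold or more in several cases. FILIP1L rose by 1.48 (SE 0.09, edgeR adjusted p = 2.39e-06) with KLF7 shRNA 1 and 1.49 (SE 0.09, edgeR adjusted p = 3.79e-06) with KLF7 shRNA 2. MAMLD1 rose by 1.47 and 1.61, the carboxypeptidase CPA4 by 1.16 and 1.28, and the ankyrin ANK3 by 1.44 and 1.13. EBI3, a cytokine subunit, rose by 1.16 and 1.10, the ephrin receptor EPHB6 by 1.135 and 1.074, and SAMD12 by 1.05 and 1.44. The dopamine receptors DRD2 and DRD1 rose by 1.04 and 1.05 with KLF7 shRNA 1 and by 1.10 and 0.93 with KLF7 shRNA 2. SCG2, a granin of secretory granules, rose by 1.59 and 0.87, and the cation channel TRPA1 by 0.85 and 1.03 (SE of these genes 0.09 to 0.20). DRD1, with 1.07 CPM in the control, lost its call with KLF7 shRNA 2 without 1 of 5 libraries (highest edgeR adjusted p = 0.107). SCG2 with KLF7 shRNA 2 (0.0636) and SAMD12 with KLF7 shRNA 1 (0.0847) lost theirs without control shRNA replicate 1B and, for SCG2, also without KLF7 shRNA 2 replicate 3. ANK3 and TRPA1 overlap genes on the other strand.

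Immediate early genes, transcribed soon after growth signals, had a mean log2 fold change of 0.28 with each hairpin. With KLF7 shRNA 1, 4 of 17 members rose and 0 fell, and with KLF7 shRNA 2, 3 rose and 1 fell. Adjusted over the list alone, 10 rose and 1 fell, and 4 rose and 1 fell. Camera gave adjusted p = 1.09e-06 and 1.11e-06, but adjusted p = 0.149 for each with an estimated correlation. FOS rose by 0.923 and 1.252, FOSB by 0.80 and 1.11, and EGR1, of the MAPK output list, by 0.67 and 0.86 (SE 0.11 to 0.15). The MAPK output list, of genes induced by ERK signalling, had a mean of 0.17 with KLF7 shRNA 1 (3 of 26 rose, 10 higher and 1 lower adjusted over the list alone) and 0.10 with KLF7 shRNA 2 (2 rose, 2 higher adjusted over the list alone). The camera test gave adjusted p = 2.22e-06 and 0.00764, and adjusted p = 0.167 and 0.445 with an estimated correlation. The per-library level of this list was highest in KLF7 shRNA 1 replicate 2, at 0.241 against 0.121 and 0.123 in the other libraries of its group, and without it the mean with KLF7 shRNA 1 was 0.12.

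**Figure D3:**
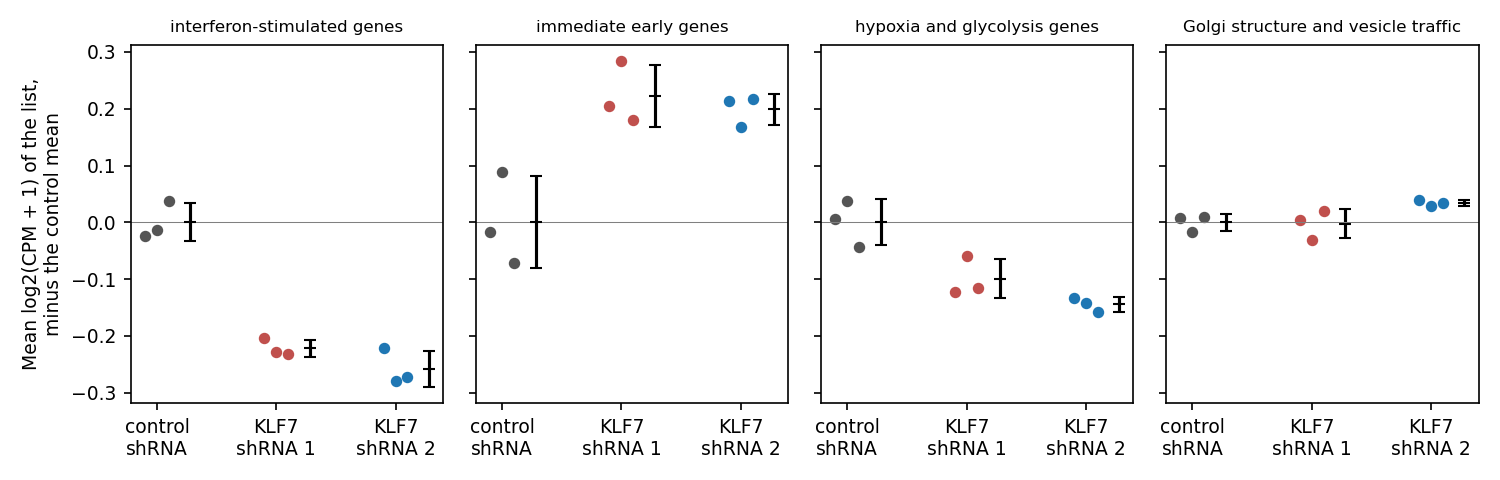
Mean log2(CPM + 1) over the tested members of 4 gene lists, minus the mean of the controls (vertical axis), in each library of the 3 groups (horizontal axis). Points are libraries and bars are the mean ± SD of 3 libraries. Interferon-stimulated genes lie 0.24 lower on average in the 6 KLF7 shRNA libraries, and the Golgi list differs by 0.02.

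Targets of NF-kB and of YAP and TEAD, mesenchymal genes and cytokines had small average increases. NF-kB target genes had means of 0.16 (2 of 22 rose; 4 adjusted over the list alone) and 0.13 (1 rose; 2 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.000814 and 0.00656, or adjusted p = 0.131 and 0.154 with an estimated correlation. YAP and TEAD target genes had means of 0.12 and 0.12, with 2 and 4 of 24 higher (8 higher and 1 lower, and 4 higher, adjusted over the list alone), and camera adjusted p = 0.00506 and 0.000995, or adjusted p = 0.122 and 0.118 with an estimated correlation. The mesenchymal list had means of 0.14 and 0.06, with 6 higher and 1 lower, then 4 higher, of 31 (10 and 2, then 5 and 3, adjusted over the list alone), and camera adjusted p = 0.00106 and 0.0283, or adjusted p = 0.149 and 0.229 with an estimated correlation. Cytokines and chemokines had means of 0.20 and 0.16, with 3 higher, then 2 higher and 1 lower, of 19 (6 and 1, then 4 and 2, adjusted over the list alone), and camera adjusted p = 0.00769 and 0.0375, or adjusted p = 0.135 and 0.154 with an estimated correlation. With no low-count filter the cytokine means were −0.237 and −0.0663 and the NF-kB mean with KLF7 shRNA 2 was −0.0774. That fit took in members too low for the main filter, with 33 cytokine and 31 NF-kB members in place of 19 and 22. With CPM above 1 in at least 3 libraries the cytokine means were 0.129 and 0.0982, and the camera call with KLF7 shRNA 2 was lost. The chemokine CXCL1 rose by 0.83 and 1.03 and IL32 by 0.70 and 0.58. THBS1, an adhesive glycoprotein, rose by 0.48 and 0.73, the metalloproteinase MMP2 by 0.54 and 0.49, N-cadherin (CDH2) by 0.40 and 0.56, and TPM1 by 0.31 and 0.36. NRG1, a ligand of ERBB receptors, rose by 0.41 and 0.50, and CLDN1, a tight junction claudin of the epithelial list, by 0.48 and 0.55 (SE of these genes 0.05 to 0.11). Of these, IL32, THBS1, MMP2, CDH2 and TPM1 overlap other genes. The camera calls for mesenchymal genes and for cytokines with KLF7 shRNA 2 were lost without 1 of 2 libraries each (highest adjusted p = 0.0952 and 0.162), and the mesenchymal mean was 0.03 without KLF7 shRNA 2 replicate 3.

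Hypoxia and glycolysis genes were lower with both hairpins, with means of −0.12 and −0.16. Of 34 members 3 fell with KLF7 shRNA 1 and 5 with KLF7 shRNA 2, and 11 and 12 fell adjusted over the list alone. Camera gave adjusted p = 0.000847 and 6.1e-09, and adjusted p = 0.212 and 0.122 with an estimated correlation. The mean with KLF7 shRNA 1 was −0.19 without control shRNA replicate 3B and −0.18 without KLF7 shRNA 1 replicate 2. Without this last library the mean with KLF7 shRNA 2, a comparison it is not part of, also moved, to −0.20. Genes were filtered anew in each of these fits. Other tested members of the list may therefore account for these shifts. PFKFB4, a regulator of glycolysis, fell by −0.44 and −0.42 and BNIP3, a mitophagy receptor with counted pseudogene copies, by −0.26 and −0.29 (SE 0.05 to 0.08). Their calls were lost in both comparisons without control shRNA replicate 1B, among others (highest edgeR adjusted p = 0.109 and 0.0873). INSIG1, which restrains sterol synthesis, fell by −0.47 and −0.60 (SE 0.05 each), while the cholesterol synthesis list as a whole did not pass camera (adjusted p = 0.979 and 0.193). Of 47 DNA replication genes, 0 and 1 rose (0 and 1 adjusted over the list alone), with means of 0.06 each and camera adjusted p = 0.0224 and 0.00577, or adjusted p = 0.135 and 0.122 with an estimated correlation. Of 25 p53 target genes 1 fell in each comparison (3 and 1 adjusted over the list alone), with means of −0.06 each and camera adjusted p = 0.0494 for both, or adjusted p = 0.154 with an estimated correlation. The camera call for DNA replication with KLF7 shRNA 1 was lost without KLF7 shRNA 1 replicate 1 (adjusted p = 0.0585), and those for p53 target genes without 1 of 8 and 1 of 6 libraries (highest adjusted p = 0.114 and 0.113).

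Golgi structure and vesicle traffic genes, 70 in number, did not pass camera in either comparison. Their mean log2 fold changes were 0.00 and 0.04 (adjusted p = 0.922 and 0.131). With KLF7 shRNA 1 the mean and the test were below 0 and the median above it. The cargo receptor TMED10 was the 1 member past the threshold in each comparison, at −0.23 and −0.30 (highest edgeR adjusted p = 0.165 and 0.0924 without 1 library). Adjusted over the list alone, 0 changed with KLF7 shRNA 1, and 1 rose and 1 fell with KLF7 shRNA 2. Of 44 Golgi glycosylation enzymes 4 rose with KLF7 shRNA 1 and 1 fell with KLF7 shRNA 2 (5 higher and 2 lower, then 2 higher and 1 lower, adjusted over the list alone). Their mean was −0.01 in each, with a median and a test direction above 0, and camera gave adjusted p = 0.368 and 0.590.

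For KLF7 shRNA 1 against the control, 242 genes rose and 186 fell, 23 and 4 of them by 2-fold or more. Extracellular matrix genes had a mean of 0.15, with 4 of 37 higher and 0 lower (10 and 1 adjusted over the list alone), secreted growth factors 0.24, with 6 of 33 higher (10 and 2 adjusted over the list alone), and TGF-beta target genes 0.16, with 3 of 23 higher (7 adjusted over the list alone). Camera gave adjusted p = 6.53e-05, 0.000134 and 0.000206, and adjusted p = 0.154, 0.154 and 0.258 with an estimated correlation. With KLF7 shRNA 2 these lists did not pass (adjusted p = 0.346, 0.389 and 0.229). KLF7 shRNA 1 replicate 2, which stands apart, had the highest levels of its group in all 3, and without it the means with KLF7 shRNA 1 were 0.12, 0.20 and 0.12. For the matrix list KLF7 shRNA 1 replicate 3 lay among the controls, at 0.00303 against −0.0657, 0.0477 and 0.018. Without control shRNA replicate 2B the TGF-beta mean was 0.27, in a fit that filtered the genes anew and may have tested other members. The matrix glycoprotein TNC rose by 1.26, FAM198B by 1.141 and GDF10 by 1.04, past the threshold here and not with KLF7 shRNA 2, where the values were 0.65, 0.77 and 0.70 (SE 0.19 to 0.25). TNC lost its call without control shRNA replicate 1B, and GDF10 without that library, control shRNA replicate 2B or KLF7 shRNA 1 replicate 1 (highest edgeR adjusted p = 0.0689 and 0.129). TNC and FAM198B overlap genes on the other strand. NRF2 target genes had a mean of 0.12, with 3 of 23 higher (6 higher and 1 lower adjusted over the list alone), and pancreatic ductal markers 0.17, with 2 of 14 higher (5 and 1 adjusted over the list alone). For these 2 lists camera gave adjusted p = 0.0494 and 0.0284, and adjusted p = 0.154 and 0.410 with an estimated correlation. These calls were lost without 1 of 5 and 1 of 2 libraries (highest adjusted p = 0.102 and 0.217). Without KLF7 shRNA 1 replicate 2 the mean of the ductal markers was 0.08, and with no low-count filter, over 23 members in place of 14, −0.111. With CPM above 1 in at least 3 libraries it was 0.151, and without KLF7 shRNA 1 replicate 2 and control shRNA replicate 3B together 0.0966. The ductal call was lost in each of these last 2 fits. The other genes the rule took were RPL15P20 and COPS8P2 (higher) and SETP4, NACA2, RPL7P26, RPL7P6 and RPS27AP11 (lower). These are pseudogenes or close copies of abundant genes, and their values are uncertain. The count of changed genes was 168 without control shRNA replicate 1B, 272 without 3B, 690 without 2B and 242 without KLF7 shRNA 1 replicate 1. The count was 168 in a fit on only the 6 libraries compared, 654 with DESeq2 and 1222 with no low-count filter.

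For KLF7 shRNA 2 against the control, 139 genes rose and 162 fell, 20 and 15 of them by 2-fold or more. ATF4 target genes, of the amino acid stress response, had a mean of −0.15, and 3 of 36 fell (6 adjusted over the list alone). Camera gave adjusted p = 5.7e-08, and adjusted p = 0.0124 with an estimated correlation. With KLF7 shRNA 1 their mean was −0.05 (adjusted p = 0.229). NUPR1, a member of this list, is given above, and PSAT1, an enzyme of serine synthesis, stood at −0.27, a call lost without 1 of 7 libraries (highest edgeR adjusted p = 0.187). PSAT1 was also lower and past the threshold with KLF7 shRNA 1 (edgeR adjusted p = 0.0200, highest 0.0719 without 1 library). Epithelial genes had a mean of −0.18, with 1 of 34 higher and 3 lower (2 and 9 adjusted over the list alone) and camera adjusted p = 0.00720, or adjusted p = 0.166 with an estimated correlation. With KLF7 shRNA 1 their mean was −0.04, against a median and a test direction above 0 (adjusted p = 0.681). MCAM, of the integrin and adhesion list, fell by −0.54 against −0.20 with KLF7 shRNA 1, and it overlaps CBL. Genes the rule took for this hairpin were EFHC2 at 1.29, DCDC2 at 1.23, TRBC2 at 0.95, IGFBP3 and PAPPA, both of insulin-like growth factor signalling, at 0.90 and 0.87, RTN4RL1 at −1.13, NMNAT3 at −1.10, KIAA1211L at −0.97, DMTN at −0.91 and KCNC1 at −0.90 (SE 0.20 to 0.26). Of these 10, EFHC2 kept its call without each library in turn, and the others did not (highest edgeR adjusted p = 0.220, for IGFBP3). None of them passed the test between the hairpins. Of the 115 genes past the threshold here and not with KLF7 shRNA 1, 114 had the same sign with KLF7 shRNA 1. These genes were selected against controls that both comparisons share, which by itself favours the same sign. The count therefore does not show that the hairpins agree. The count of changed genes was 133 without control shRNA replicate 1B, 197 without 2B, 160, 127 and 122 without KLF7 shRNA 2 replicate 1, 2 and 3, and 580 without KLF7 shRNA 1 replicate 2. The count was 487 in a fit on only the 6 libraries compared and 646 with no low-count filter.

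Averaged over both hairpins, 248 genes rose and 268 fell against the control, 18 and 14 of them by 2-fold or more. KLF7 itself fell by −0.39 (SE 0.08, edgeR adjusted p = 0.0208) and DLG3 by −0.62 (SE 0.09, edgeR adjusted p = 0.000983). The count of changed genes was 216, 333, 305 and 330 without control shRNA replicate 1B, control shRNA replicate 3B, KLF7 shRNA 2 replicate 2 and KLF7 shRNA 2 replicate 3.

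The last comparison set the hairpins against each other. SPNS2, a sphingosine-1-phosphate transporter, and VGF, a neuropeptide precursor, were higher with KLF7 shRNA 1, and these were the 2 genes past the threshold by edgeR, with 2237 at an unadjusted p under 0.05. SPNS2 stood at 8.54 ± 0.724 CPM with KLF7 shRNA 1 and 3.74 ± 0.173 with KLF7 shRNA 2 (SD, n = 3 each), a log2 difference of 1.18 (SE 0.12, edgeR adjusted p = 0.00126), and 4.89 ± 0.616 in the control. It overlaps MYBBP1A on the other strand. VGF stood at 20.4 ± 3.10 CPM with KLF7 shRNA 1, with a log2 difference of 0.76 (SE 0.11, edgeR adjusted p = 0.0463). The VGF call was lost without 1 of 5 libraries (highest edgeR adjusted p = 0.554). KLF7 differed by 0.18 (SE 0.10, edgeR adjusted p = 0.443). DESeq2 called 24 genes and limma-voom called 1. With no low-count filter the count was 325, of which 250 were higher and 75 lower with KLF7 shRNA 1.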

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

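Of the tests below, the count of shared genes in splits that keep the real controls was chosen after the result was seen. SPNS2 (log2 difference 1.18) and VGF (0.76) responded differently to the hairpins by the test of the difference itself, both higher with KLF7 shRNA 1. The same test by camera, on the mean log2 difference between KLF7 shRNA 1 and KLF7 shRNA 2, passed for 13 of 41 lists, and 0 of these passed with an estimated correlation. The means were 0.15 for secreted growth factors, 0.0720 for MAPK output genes, 0.10 for ATF4 target genes, 0.15 for epithelial genes and 0.13 for extracellular matrix genes. They were 0.0756 for integrins and adhesion, 0.0610 for ribosomal protein genes, 0.0784 for lysosome and autophagy genes, 0.11 for NRF2 target genes and 0.12 for TGF-beta target genes. They were 0.16 for Notch target genes, 0.16 for fibroblast markers (6 tested members) and 0.34 for endothelial markers (3 tested members). The calls for MAPK output genes, ribosomal protein genes, fibroblast markers and endothelial markers were lost without 1 of 1 to 3 libraries (highest adjusted p = 0.0681, 0.112, 0.152 and 0.123). Without KLF7 shRNA 1 replicate 2 the means were 0.03 for MAPK output genes, 0.03 for integrins and adhesion and 0.08 for TGF-beta target genes, and without KLF7 shRNA 1 replicate 1 the mean of the fibroblast markers was 0.10. The lowest of their p-values was adjusted p = 0.0911 with an estimated correlation, for ATF4 target genes. Of 10 splits of the 6 libraries, the real one gave 2 genes and the highest other 1, and 10 splits are too few for a share under 0.05.

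The changes of the 2 hairpins against the control were alike, though part of this likeness is also seen in the simulations of unchanged groups. Over all tested genes 66.7% had the same sign, against 66.8% simulated, and the correlation was 0.613 against 0.504. The covariance exceeded the variance of the control mean by 0.0150 (bootstrap over genes 0.0135 to 0.0166). Over genes with a mean CPM of 5 or more the excess was 0.00789 (0.0069 to 0.0089). In the simulations 1 gene at most was shared, against 186. They held no changed gene, so few genes could be called and shared, whatever the controls added. That count cannot decide. The excess covariance argues against shared control libraries as the whole account. The bootstrap resamples genes and the simulations draw each gene on its own. Neither holds deviations that the genes of 1 control library share, so a part from the shared controls stays open. A preparation batch cannot be told apart from the control hairpin, since all 3 control libraries and none of the KLF7 shRNA libraries carry a B in their replicate label and the labels give no batch. Lower KLF7 in both lines stays open as the biological explanation. The shared genes moved 1.00 times as far with KLF7 shRNA 2 as with KLF7 shRNA 1 (bootstrap over genes 0.963 to 1.04). These genes were selected as past the threshold in both comparisons against the same controls. That selection and the common controls can draw the ratio toward 1, so it cannot decide. The KLF7 log2 fold changes had a ratio of 1.62 but did not differ past the threshold (unadjusted p = 0.0846, edgeR). Of 840 splits of the 9 libraries into 3 groups, 100 were drawn. Of these, 1 gave as many as 186 shared genes, the real one, and the highest other gave 0. The draw held 0 of the 9 other splits that keep the real controls and mix the hairpins, and these shared 131 to 174 genes. Each other drawn split therefore mixed control with KLF7 shRNA libraries. No such mixing gave shared genes, but the draw cannot tell whether the 2 hairpins act alike. With 1 control hairpin and replicates that may be technical, it does not exclude a chance difference of the control line.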

How the results depend on the processing

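The fit without KLF7 shRNA 1 replicate 2 and control shRNA replicate 3B together was chosen after seeing the data. Interferon-stimulated genes stayed lower and past the camera threshold in both comparisons under each alternative for lists, with means of −0.24 to −0.29 and −0.31 to −0.36. RLE and upper-quartile factors moved no count of changed genes by more than 1.5 times. The counts that did move follow, and where fewer libraries or genes were used the cause was not tested further.

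With no low-count filter the counts were 1222 for KLF7 shRNA 1, 646 for KLF7 shRNA 2, 350 shared, 963 averaged and 325 between the hairpins. At an adjusted p under 0.01 they were 149, 134, 86, 207 and 1. DESeq2 gave 654 for KLF7 shRNA 1 and 24 between the hairpins. In fits on only the libraries compared they were 168 for KLF7 shRNA 1, 487 for KLF7 shRNA 2 and 1 between the hairpins. Between the hairpins limma-voom and the filter of CPM above 1 in at least 3 libraries gave 1 gene each. With both libraries that stand apart left out there were 994 for KLF7 shRNA 2, 369 shared, 924 averaged and 9 between the hairpins. Leaving out 1 library at a time gave 168 to 690 for KLF7 shRNA 1, 122 to 580 for KLF7 shRNA 2, 88 to 259 shared, 216 to 745 averaged and 1 to 9 between the hairpins. KLF7 log2 fold changes ran from −0.32 to −0.27 with KLF7 shRNA 1 and from −0.57 to −0.37 with KLF7 shRNA 2, where the call was lost without 4 of the libraries.

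With the replicate number as a replicate block, taking 1B, 2B and 3B as 1, 2 and 3, there were 823 genes for KLF7 shRNA 1 and 6 between the hairpins, and 229 shared. The numbers do not pair the libraries: the deviations of same-numbered libraries correlated from −0.24 to 0.35, with 1 of 9 pairs over 0.1, and the best match had the same number in 5 of 18 cases.

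With an estimated correlation 3 of 82 list tests passed in place of 27. The estimates lay above the preset 0.01 for some lists, such as MAPK output genes (0.17 in each comparison). For others they lay below it, such as cytokines and chemokines (−0.01249 and −0.01295) and p53 target genes (−0.035 and −0.034). The calls lost for such lists therefore do not come from a higher correlation. For interferon-stimulated genes with KLF7 shRNA 1 the estimate, 0.014, was near the preset. Their camera adjusted p still went from 3.79e-17 to 0.00677. The repeat thus differs from the preset test in more than the correlation, and the drop from 27 to 3 cannot be credited to correlation alone. The mean of the Golgi structure list with KLF7 shRNA 1, near 0, turned positive with no low-count filter (0.00218) and with both libraries left out (0.0163), and ran from −0.0115 to 0.0124 without 1 library; it passed in none of these. With no low-count filter the means turned negative for cytokines and chemokines (−0.237 and −0.0663), NF-kB target genes with KLF7 shRNA 2 (−0.0774), pancreatic ductal markers with KLF7 shRNA 1 (−0.111) and endothelial markers between the hairpins (−0.0354). Members too low for the main filter entered these lists, so the means are over other sets of genes. HOXC6, never past the threshold, changed sign with KLF7 shRNA 1 without control shRNA replicate 3B (−0.0041), without KLF7 shRNA 1 replicate 2 (−0.0428) and without both (−0.0666), and with KLF7 shRNA 2 without KLF7 shRNA 2 replicate 2 (0.0299). Its highest value with KLF7 shRNA 1 was 0.0864 and its lowest with KLF7 shRNA 2 −0.0545, each without replicate 3 of that hairpin. FTH1 with KLF7 shRNA 2, also never past it, did so without control shRNA replicate 3B (−0.0595) and without both (−0.061), and its highest value was 0.193, without control shRNA replicate 2B. Of 174 calls on named genes, 99 held without each library in turn, and of 40 calls on lists that passed, 29 held. In its 1 draw, at the depths and spread of these libraries, the self-test recovered 60% and 72% of 1.5-fold changes, so many small changes go uncalled. The same genes were changed alike in both groups, so the gap between these 2 values may be noise of the draw.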

Other observations

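Of the tests below, the rise that thinning gave the other libraries was chosen after the result was seen. Several further lists described the cells without passing camera in either comparison. Antigen presentation genes, which interferon also raises, had mean log2 fold changes of 0.09 and 0.06 (0 of 21 past the threshold in each, camera adjusted p = 0.0856 and 0.182), against −0.27 and −0.32 for the interferon-stimulated list. By fry the antigen presentation list was higher in both comparisons (fry adjusted p = 0.0155 and 0.0445). Interferon receptors and regulators had means of 0.05 and −0.03 (adjusted p = 0.413 and 0.922, the second mean below 0 against a test direction above it), with SOCS3, an inhibitor of cytokine signalling, higher by 0.39 with KLF7 shRNA 1. The Krüppel-like and SP factors had means of −0.05 and −0.08 (camera adjusted p = 0.452 and 0.347), and fry called them lower in both (fry adjusted p = 0.0459 and 0.0219). KLF4 rose by 0.54 with KLF7 shRNA 1, a call lost without 1 of 4 libraries (highest edgeR adjusted p = 0.119). Mitosis genes had means of 0.00 and 0.04 (adjusted p = 0.988 and 0.131) and oxidative phosphorylation genes of 0.00 and −0.01 (adjusted p = 0.960 and 0.616). With KLF7 shRNA 1 the mean, median and test of these 2 lists differed in sign. Leukocyte markers had 6 tested members and 0 past the threshold.

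Lower interferon-stimulated genes with both hairpins were not set by 1 library: the smallest share of the mean left without any 1 library was 0.930. The highest adjusted p was 8.34e-13, by camera with the preset correlation. The repeat with an estimated correlation, which gave adjusted p = 0.00677 and 0.00520 with all libraries, was not run with a library left out. A trend on GC content and exon length does not account for them, since after its removal the means were −0.26 and −0.33, below each of 10000 random lists matched on expression. Interferon activity particular to the control line cannot be told apart from an effect of both hairpins, because there is 1 control hairpin; the list differed by 0.0508 between the KLF7 shRNAs. An effect of lower KLF7 is a candidate explanation that these libraries leave open.

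KLF7 shRNA 1 replicate 2 and, next to it, control shRNA replicate 3B deviated most from their groups, with root mean square deviations of 0.198 and 0.180 (log2 scale). A smooth trend on GC content and exon length took up 32.2% of the variance of the first library's deviation over all genes and 49.9% over genes with a mean CPM of 5 or more, so such a trend may account for part of it. After all libraries were thinned to the smallest total its deviation was 1.09 times that of the next, against 1.10 times before, so the 1.2 times set in advance could not have been reached. In 20 draws, thinning raised the deviation of any other library by at most 6.72% of the gap between this library and the median of the others, which argues against library size as the cause. No biological explanation was tested.

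Splits of the libraries bear on the counts of changed genes. For KLF7 shRNA 1 the real split gave 428 genes, with 1 of 10 splits as large and 0 as the highest other, and for KLF7 shRNA 2 it gave 301, with 1 of 10 and 0. In each, 10 splits are too few for a share under 0.05. For both hairpins together against the control, the 2-group fit gave 403 genes. Of 84 splits, 1 was as large, the real one, and the highest other gave 1. No other division of these libraries gave such a count. With 1 control hairpin and replicates that may be technical, the splits cannot exclude a chance difference between the lines.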
